A study of Oryza sativa Indica Group with 8 samples.

How the data were processed

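Roots of Oryza sativa Indica Group seedlings were measured on the Affymetrix rice array, 8 arrays in all, with 2 arrays in each of 4 groups: control, P deficiency, Fe deficiency and both. Per the labels, RNA was extracted with a Sigma Spectrum plant kit and labelled with biotin. Per the submitters' processing notes, the values were made in Affymetrix Expression Console 1.1. The method that turned probe signals into probe set values is not given in the sources used here. The deposited values are array intensities on a linear scale, 1 per probe set and array. The mean intensity after leaving out the lowest and highest 2% of probe sets was 500.07 on each deposited array, as from scaling to a target of 500. No detection calls came with the values, and all data columns were used.

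The deposited table held 57381 probe sets. The 123 AFFX control probe sets and 64 RPTR reporter probe sets were left out, which left 57194 for testing. The AFFX spikes and the 3' to 5' differences of control transcripts were kept as measures of array quality. Of the probe sets, 22436 matched exactly 1 gene in the probe table used here, 95 matched several, and 34663 had no gene there, so counts of probe sets cover sequences that cannot be named here. The 22436 probe sets represented 17905 genes, of which 2452 had a name other than a locus or clone number and 3444 had several probe sets. The gene table describes a japonica rice assembly, while the plants were Indica, so a sequence difference between them can lower the signal of a probe set. Genes are given by name with their locus number, and some names are shared by 2 loci.

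Intensities of the 57194 probe sets were quantile-normalized across the 8 arrays and converted to log2(intensity + 16). The added 16 damps the noise of dim probe sets and understates their fold changes, and a fold is given on this scale. This setting for linear values was set before the data were examined. Each probe set was fitted with 1 mean per group on all 8 arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 4 residual and 1.74 prior degrees of freedom). All p-values of genes are moderated limma p-values, adjusted by the Benjamini-Hochberg method over the 57194 probe sets, with a threshold of 0.05. Standard errors are those of the same fit. The 6 contrasts were each deficiency against the control, the combined deficiency against each single deficiency, and the interaction. "Rose" and "fell" are used for probe sets that passed, and a count "adjusted over the list alone" repeats the adjustment within 1 list.

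With 2 arrays per group, the precision came from pooling the spread over all 4 groups. Where an array was left out, the single array of its group was assumed to vary like those of the other groups. The replicate numbers were not treated as pairs. No label says whether the replicates came from separate cultures.

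Named genes followed a rule set before the data were examined. A gene was eligible with an adjusted p under 0.05, an absolute log2 change of at least 1, a match to exactly 1 gene, a name, and both arrays of 1 group above both arrays of the other. The 10 largest rises and 10 largest falls were named for each contrast with the control, and 5 of each for the other contrasts, 1 probe set per gene. The planned check of gene descriptions was not possible, as the tables used here hold names only, so genes without a name were passed over. The requirement on single arrays does not apply to the interaction. Members of the gene lists are named as well, the fixed ones by list and of the others up to 3 per list.

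Gene lists were tested with limma camera on 1 probe set per gene, the one with the highest mean, with the preset correlation between genes of 0.01. Counts of list members that passed refer to the same probe sets. The p-values were adjusted over the 41 lists with at least 5 measured genes in each contrast, and 5 smaller lists were not tested. Camera adjusted p-values with a correlation estimated from the residuals are given beside each call. That estimate rests on 4 residual degrees of freedom. It was below the preset 0.01 for some lists, such as -0.0294 for phosphate starvation and -0.00903 for iron acquisition. For such lists a larger p-value does not come from a stronger correlation between genes. Some lists were fixed by member and the rest were to be drawn by keyword from gene descriptions. A fixed member counts as measured if it was matched by name and had a probe set listed. This left 9 of 21 phosphate starvation genes, 9 of 13 PHT1 transporters, 10 of 18 iron acquisition genes and 2 of 12 iron regulators. As no descriptions were at hand, the keyword lists were drawn by patterns in gene names. A few lists were added or changed once the gene tables were seen and before any array value was examined.

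Agreement between contrasts was described by correlation across probe sets, with no p. Overlaps were set against the number that independent lists would share, and contrasts with common control arrays against 100 simulations of unchanged groups. The P and Fe effects were also compared with a different control array for each, a check chosen after the data were seen. Alternatives were other scalings, pseudocounts of 1 and 64, filters on low probe sets, trend and robust eBayes, array weights, a replicate block (statmod 1.5.0), other probe set choices, stricter thresholds, fry in place of camera, only the arrays of the contrast, and each array left out in turn. The deposited scaling alone was added after the data were seen.

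The workflow was tested on simulated data with the numbers of probe sets and arrays of the data, where 200 of 57194 probe sets were changed in P deficiency. It recovered 0% of changes with a log2 size of 1 and 52% of those with a size of 2. It called 2 unchanged probe sets and gave a slope of 1 of estimated on true change. In the data 4736 probe sets were called in P deficiency. With fewer changed probe sets the adjusted threshold is stricter, so the shares recovered do not describe that contrast. Figures were drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.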

Results

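Transcript levels were measured in roots of rice (Oryza sativa, Indica Group) on 8 Affymetrix arrays, 2 for each of 4 nutrient treatments. The groups were a control, plants deprived of phosphorus (P), plants deprived of iron (Fe) and plants deprived of both. The submitters' design text gives 7 days of treatment, while their protocol notes give 10 days of hydroponic growth and seedlings 5 days old. How these times fit together is not given in the sources used here. Each array held values for 57381 probe sets, of which 57194 were not control probe sets and were tested. Before quantile normalization the median intensity of an array ranged from 48.0 to 68.9, and the group means of these medians were 51.2 in the control, 62.5 in P deficiency, 50.7 in Fe deficiency and 66.4 in the combined deficiency. Across probe sets, which are not independent replicates, the 2 arrays of a group correlated at 0.965 to 0.974. The control arrays correlated at 0.965 with each other and at up to 0.966 with an array of another group. No label says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision. Gene values below are quantile-normalized intensities given as group means ± SD (n = 2 arrays per group), with changes on the log2(intensity + 16) scale, which understates the change of dim genes. Without detection calls, a mean below the array medians is not shown to lie above background, so the size of a change from such a mean depends on the added 16.

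The first comparison asked what withholding P changed in roots supplied with Fe. The 6 largest rises among named genes were those of phosphate starvation genes. OsSPX3 (LOC4348535), which encodes an SPX domain protein that senses phosphate status, went from 20.6 ± 13.8 in the control to 2221 ± 255 in P deficiency, a log2 change of 5.98 (SE 0.293, limma adjusted p = 0.00384). OsMGD2 (LOC4345212), a monogalactosyldiacylglycerol synthase that replaces phospholipid with galactolipid, went from 24.6 ± 4.10 to 1829 ± 75.6 (5.51, SE 0.157, adjusted p = 0.00123). The transporter gene OsPT6 (OsPht1;6, LOC4346342) went from 52.7 ± 38.4 to 1450 ± 136, a 23.2-fold rise (SE 0.382 on the log2 scale, adjusted p = 0.00743).

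Of the 9 measured members of the phosphate starvation list, 8 rose and 0 fell over all probe sets, and 8 rose when adjusted over the list alone. The median change was 3.53 (camera adjusted p = 1.08e-06, and adjusted p = 0.0986 with an estimated correlation). Besides OsSPX3, OsMGD2 and OsPT6, the members that rose were OsSPX5 (log2 change 5.05), OsSPX2 (3.53), OsSPX1 (3.39), OsPT2 (1.41) and OsMGD3 (1.04). Among the 9 measured PHT1 phosphate transporters 2 rose and 1 fell, also when adjusted over the list alone. The one that fell was OsPT1 (LOC4331635), at 4189 ± 369 in the control and 1593 ± 42.7 in P deficiency (-1.38, adjusted p = 0.00907). A second, dim OsPT1 probe set gave 1.77 (adjusted p = 0.213). Of the 5 measured phosphate signalling regulators only OsPHR3 passed (-0.85, adjusted p = 0.0453). The SPX domain list (4 of 7 rose, also when adjusted over the list alone, camera adjusted p = 0.00474) and the membrane lipid list (2 of 5 rose, also when adjusted over the list alone, camera adjusted p = 0.0128) hold the same SPX and MGD genes. Those calls had adjusted p = 0.171 and adjusted p = 0.189 with an estimated correlation.

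**Figure D1:**
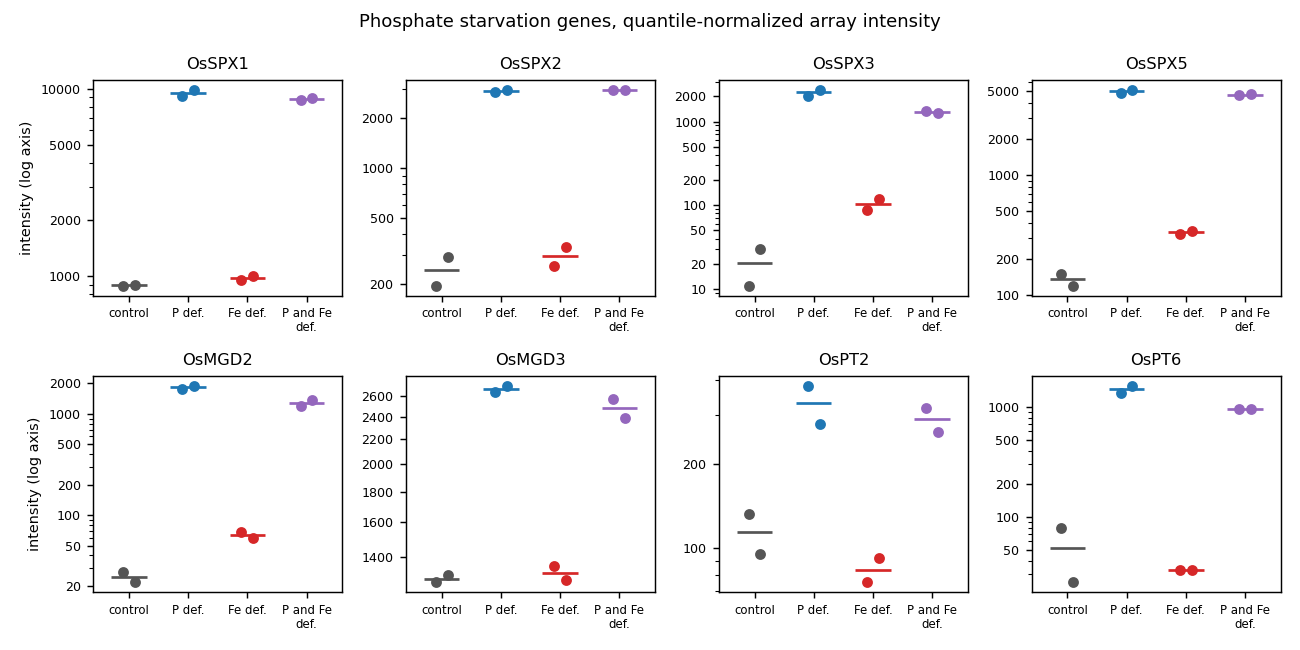
Quantile-normalized array intensity (log axis) of 8 phosphate starvation genes in the control, P deficiency, Fe deficiency and combined deficiency; points are single arrays and bars are means of 2 arrays. In each panel the 2 arrays of P deficiency and the 2 arrays of the combined deficiency lie above the arrays of the other groups, for example at a mean of 9543 and 8819 for OsSPX1 against 893.8 in the control and 977.3 in Fe deficiency.

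Other genes among the 10 largest named rises were OsP5CS2 (LOC4324853, log2 change 3.25), a proline synthesis enzyme, OsCHS1 (LOC4350636, 2.94), a chalcone synthase at the entry to flavonoid synthesis, a lectin gene named Agglutinin (LOC4335068, 2.66) and AMY1.1 (LOC4330832, 2.45), an alpha-amylase. The largest named fall was that of OsZIP1 (LOC4326394), of the zinc and iron transporter family, from 1736 ± 183 to 203 ± 1.81 (7.99-fold lower, SE 0.296 on the log2 scale, adjusted p = 0.00907). The copper transporter genes OsCOPT1 (LOC4324610) and OsCOPT2 (LOC4338846) fell by 2.12 and 1.93 on the log2 scale. OsPLP2 (LOC4345833) was at -2.46, OsDREB1B.1 (LOC4347618), a transcription factor of the DREB1 family, at -2.40, and OsBURP16 (LOC4348595) at -2.07. OsWRKY71 (LOC4328512, -1.97), CCS1 (LOC4334251, -1.92), the chloroplast aldolase gene ALDP (LOC4349897, -2.03) and the light-regulated gene LIR1 (LOC4326442, -1.91) completed the 10 largest named falls. The lower level of OsDREB1B.1 was not particular to P deficiency. It stood at 785 in the control, 139 in P deficiency, 120 in Fe deficiency and 137 in the combined deficiency.

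Lists set as markers of dividing cells shifted upward in P deficiency. The mitotic list was drawn by gene name and holds mostly kinesins and cyclins. Whether each of these genes acts in dividing cells was not tested. Of its 42 measured genes 17 rose and 1 fell, and 28 rose and 2 fell when adjusted over the list alone (median 0.73, camera adjusted p = 2.09e-07, and adjusted p = 0.0928 with an estimated correlation). The kinesin KIN14B (LOC9267695) went from 188 to 839 and KIN14C (LOC4326167) from 401 to 1235. Of 5 histone genes 2 rose, and 3 when adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.32 with an estimated correlation). Of 25 cytosolic ribosomal protein genes 5 rose and 3 fell, and 12 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.171 with an estimated correlation). Among 29 cellulose synthase and related genes 10 rose and 1 fell, and 14 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00976, and adjusted p = 0.171 with an estimated correlation). OsCslC3 (LOC4345095, 2.00) and OsCslF6 (LOC4344719, 1.71) led that list.

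Of the 6 root tissue markers 4 rose and 2 fell, also when adjusted over the list alone, and the list as a whole was not called (camera adjusted p = 0.215). The secondary-wall cellulose synthases OsCESA4 (1.41), OsCESA7 (0.97) and OsCESA9 (1.42) and the Casparian strip gene OsCASP1 (LOC4337453, 1.77) rose, while the silicon transporter genes OsLsi1 (-0.67) and OsLsi2 (-1.31) fell. Photosynthesis genes, fixed as markers of shoot tissue, moved the other way. Of 8 measured, 5 fell and 0 rose, and 7 fell when adjusted over the list alone (median -1.26, camera adjusted p = 0.000291, and adjusted p = 0.189 with an estimated correlation). The Rubisco small subunit gene OsrbcS (LOC4351966) stood at 10680 in control roots and 3654 in P deficiency.

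A further 4 lists shifted downward in P deficiency, those of heavy metal ATPase, MTP and COPT, jasmonate, WRKY and protein phosphatase 2C genes. The pathogenesis-related list was not called (1 of 11 rose and 1 fell, also when adjusted over the list alone, camera adjusted p = 0.757). Of 12 heavy metal ATPase, MTP and COPT genes 5 fell, and 7 when adjusted over the list alone (median -0.62, camera adjusted p = 0.00225, and adjusted p = 0.171 with an estimated correlation). Of 34 jasmonate genes 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone. That list had camera adjusted p = 0.0468, and adjusted p = 0.237 with an estimated correlation. OsJAZ10 (LOC4331834, -1.40) and AOS3 (LOC4328742, -1.57) were among them. Of 6 WRKY genes 2 fell, and 3 when adjusted over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.237 with an estimated correlation). Of 55 protein phosphatase 2C genes 7 fell and 1 rose, and 12 fell and 4 rose when adjusted over the list alone (camera adjusted p = 0.0468, and adjusted p = 0.259 with an estimated correlation). Iron acquisition genes went both ways and were not called as a group (3 rose and 1 fell of 10, 4 and 2 when adjusted over the list alone, camera adjusted p = 0.552). OsNAS1 (0.85), OsNAS2 (0.88) and OsIRT1 (0.98) rose and OsNAAT1 (LOC9267778) fell by 0.92 on the log2 scale. The vacuolar iron transporter gene OsVIT1 (LOC4336075, 1.70) and the nicotianamine synthase gene OsNAS3 (LOC4344361, 0.84) rose as well.

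In all, 4736 probe sets changed in P deficiency, 2417 upward and 2319 downward, of which 1641 and 1456 changed by at least 2-fold, in 2927 genes with a known probe set. With each array centred on its own median the share called upward was 32.8% in place of 51%. The count was 6 and 3 without P deficiency replicate 1 or 2, 1013 and 1378 without control replicate 1 or 2, 1920 and 1872 without an Fe-deficiency array, and 2990 and 2985 without an array of the combined deficiency. It was 0 in a limma fit on the 4 arrays of these groups alone, where 11222 probe sets had an unadjusted p below 0.05.

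The second comparison asked what withholding Fe changed in roots supplied with P. The genes of mugineic acid synthesis and uptake, by which grasses take up ferric iron, were higher. OsNAS2 (LOC4332607), a nicotianamine synthase, went from 3272 ± 342 to 13150 ± 88.1, a log2 change of 2.01 (SE 0.146, limma adjusted p = 0.0244). OsNAS1 (LOC4332608) went from 8097 ± 340 to 25050 ± 450 (1.63, SE 0.143, adjusted p = 0.0366), and OsYSL15 (LOC9268232), the transporter of iron complexed to deoxymugineic acid, from 460 ± 31.4 to 1862 ± 266 (1.98, SE 0.174, adjusted p = 0.0366).

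Of the 10 measured iron acquisition genes 3 rose over all probe sets, and 9 rose when adjusted over the list alone. The median was 1.26 (camera adjusted p = 1.72e-16, and adjusted p = 0.0337 with an estimated correlation). This was the only list of any comparison whose call held with an estimated correlation. Members short of the threshold over all probe sets were OsNRAMP1 (LOC4342862) at 764 and 2921 (1.92, adjusted p = 0.0555), OsYSL9 (LOC4336545) at 616 and 1581 (1.34, adjusted p = 0.0645) and OsNAAT1 at 7615 and 13230 (0.80, adjusted p = 0.134). The ferrous transporter gene OsIRT1 (LOC4333669) was dim, at 116 and 170 (0.49, adjusted p = 0.52). The regulator OsIRO3 (LOC4332972) gave 1.17 (adjusted p = 0.167) and the vacuolar transporter gene OsVIT2 (LOC4346978) -0.95 (adjusted p = 0.32). The YSL and Nramp list, which shares OsYSL15, OsYSL9, OsYSL16, OsNRAMP1 and OsNRAMP5 with it, had 1 of 21 genes higher and 5 when adjusted over the list alone (camera adjusted p = 0.000188, and adjusted p = 0.145 with an estimated correlation).

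**Figure D2:**
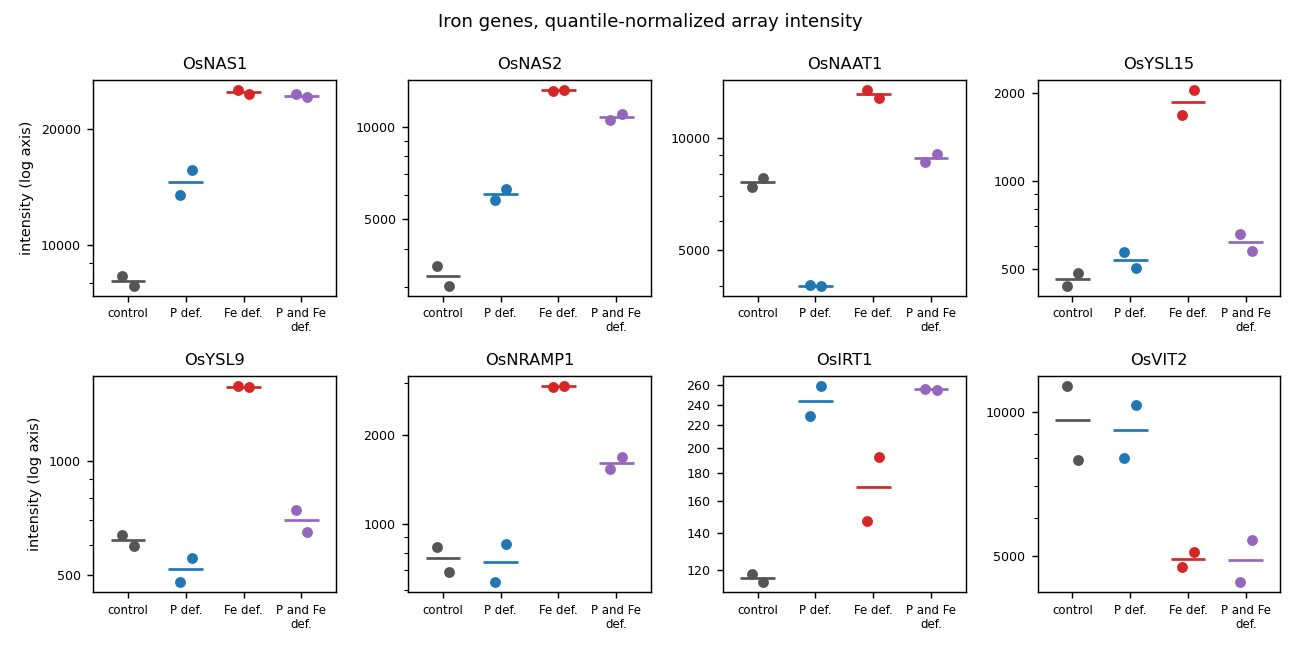
Quantile-normalized array intensity (log axis) of 8 iron genes in the 4 groups; points are single arrays and bars are means of 2 arrays. OsYSL15 had a mean of 1862 in Fe deficiency and 616.6 in the combined deficiency, against 459.8 in the control, while OsNAS1 had 25050 and 24480 against 8097.

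On the scale used the largest named rise in Fe deficiency was that of AMY1.1 (LOC4330832), from 20.4 ± 24.7 in the control to 20170 ± 1160 (9.30, SE 0.507, adjusted p = 0.0101). Its control arrays, at 37.9 and 2.92, lay below the array medians, so the size of this rise is inexact. LTP2-B (LOC4351317), a lipid transfer protein, went from 17.2 ± 2.25 to 2040 ± 68.1 (5.95, adjusted p = 0.000982). The other LTP2-B probe sets gave 4.11 (adjusted p = 0.0731) and 1.05 (adjusted p = 0.367). The glutaredoxin GRXC10 (LOC4351046) went from 26.5 to 619 (3.95) and ACA1 (LOC4326507) from 4.84 to 77.5 (2.17). The remaining named rises were those of the metallothioneins OsIDS1 (LOC4352580, 1.93) and OsMT-I-2c (LOC4337596, 1.93) and of ML (LOC4326471, 1.73). Of the genes with a name other than a locus or clone number, only CML15 (LOC4338633), a calmodulin-like protein, was eligible among the falls, from 1412 ± 160 to 372 ± 33.5 (-1.88, adjusted p = 0.0294).

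**Figure D3:**
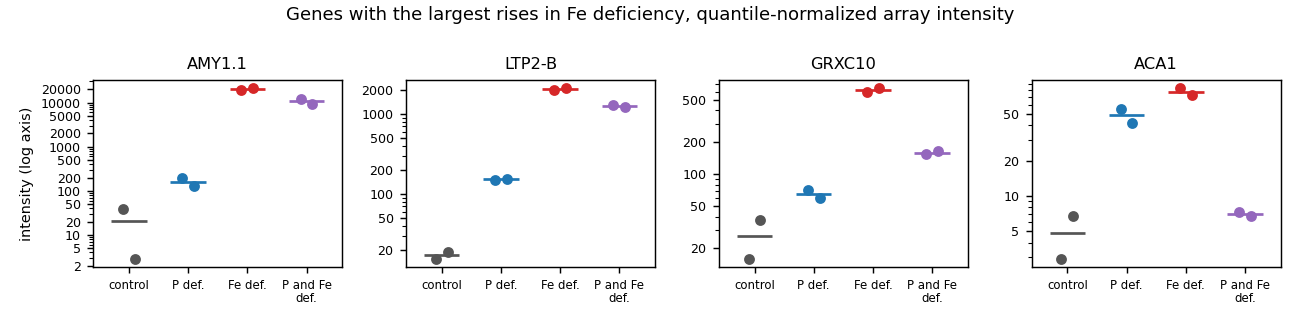
Quantile-normalized array intensity (log axis) of the 4 genes with the largest named rises in Fe deficiency, in the 4 groups; points are single arrays and bars are means of 2 arrays. AMY1.1 had a mean of 20170 in Fe deficiency and 10830 in the combined deficiency, and ACA1 had 77.53 and 7.015.

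Of 7 metallothioneins 2 rose and 3 when adjusted over the list alone (camera adjusted p = 1.51e-07, and adjusted p = 0.0643 with an estimated correlation). Among 11 pathogenesis-related genes the chitinase Cht1 (LOC4338719) rose from 784 to 2412 (1.60, adjusted p = 0.0294), and 6 rose when adjusted over the list alone (camera adjusted p = 3.43e-08, and adjusted p = 0.13 with an estimated correlation). Of 19 diterpenoid phytoalexin genes 0 passed over all probe sets and 5 were higher when adjusted over the list alone (median 0.71, camera adjusted p = 2.7e-07, and adjusted p = 0.0643 with an estimated correlation). CYP99A2 (LOC4335096) stood at 314 in the control and 791 in Fe deficiency. The phosphate starvation list had 0 members passing and 3 higher when adjusted over the list alone (camera adjusted p = 0.0382, and adjusted p = 0.227 with an estimated correlation). These 3 were OsSPX3 (20.6 and 103), OsSPX5 (136 and 335) and OsMGD2 (24.6 and 64.1). SPX domain proteins, with 2 of 7 higher when adjusted over the list alone, had camera adjusted p = 0.0253, and adjusted p = 0.227 with an estimated correlation. Photosynthesis, mitotic and glutathione S-transferase genes had 0 members passing, also when adjusted over the list alone, and negative medians of -0.37, -0.11 and -0.21. Their camera adjusted p were 0.000751, 0.0424 and 0.0433, with adjusted p = 0.227, 0.227 and 0.241 with an estimated correlation.

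In all, 71 probe sets changed in Fe deficiency, 60 upward and 11 downward, each by at least 2-fold, in 40 genes with a known probe set. The count was 0 without Fe deficiency replicate 2 (4113 at an unadjusted p below 0.05 in limma) and 4 without replicate 1, 9 without either control array, 10 without either P-deficiency array and 8 without either array of the combined deficiency. It was 0 in a limma fit on the 4 arrays of these groups alone, where 5009 probe sets had an unadjusted p below 0.05.

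The third comparison set the combined deficiency against the control. AMY1.1 went from 20.4 ± 24.7 to 10830 ± 2046 (log2 change 8.40, SE 0.507, limma adjusted p = 0.00782) and LTP2-B from 17.2 ± 2.25 to 1274 ± 52.0 (5.28, SE 0.135, adjusted p = 0.00065). Of the other LTP2-B probe sets 1 was higher, at 30.1 in the control and 383 in the combined deficiency. The other, a dim one, was not, at 21.2 and 14.2. Phosphate starvation genes rose in 7 of 9 cases, and in 8 when adjusted over the list alone (median 3.54, camera adjusted p = 2.62e-07, and adjusted p = 0.0918 with an estimated correlation). OsSPX3 reached 1293 ± 41.3 (5.21), OsMGD2 1295 ± 119 (5.01), OsSPX5 4667 ± 52.6 (4.96) and OsPT6 950 ± 1.85 (3.94). Of the iron acquisition genes 3 of 10 rose, and 5 when adjusted over the list alone (median 0.73, camera adjusted p = 0.00132, and adjusted p = 0.148 with an estimated correlation). OsNAS2 (1.71), OsNAS1 (1.60) and OsIRT1 (1.05) passed, whereas OsYSL15 stood at 617 ± 57.6 (0.41, adjusted p = 0.274).

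The other named rises were those of the Agglutinin gene (3.59), OsSPX2 (3.54), the beta-expansin OsEXPB18 (LOC4338206, 3.50) and OsSPX1 (3.28). The falls were led by CBF3 (LOC4347620), a DREB1-family factor, from 643 ± 73.8 to 88.3 ± 25.9 (-2.68, adjusted p = 0.0131), OsDREB1B.1 (-2.41) and OsZIP1 (-2.31). OsSFR2 (LOC4351127, -2.09), the trehalose-phosphate phosphatase OsTPP4 (LOC4330753, 4.01-fold lower), MYBS2 (LOC4349391, -1.95), OsGLU15 (LOC4345463, -1.94), OsCOPT1 (-1.72), the expansin OsaEXPb2.2 (LOC4349265, -1.67) and CDKE-1 (LOC4349519, -1.63) followed. Each single deficiency also had a lower level of CBF3, at 166 without P and 194 without Fe. The diterpenoid phytoalexin genes rose in 6 of 19 cases, and in 12 when adjusted over the list alone (median 1.15, camera adjusted p = 4.26e-05, and adjusted p = 0.0918 with an estimated correlation). OsCPS2 (LOC9266189), a copalyl diphosphate synthase, went from 191 to 1290 (2.71) and CYP701A8 (LOC4341343) from 578 to 1405 (1.25).

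Mitotic genes rose in 3 of 42 cases and fell in 1, and 13 rose and 1 fell when adjusted over the list alone (median 0.45, camera adjusted p = 5.05e-05, and adjusted p = 0.0918 with an estimated correlation). Of 29 cellulose synthase and related genes 6 rose, and 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0153, and adjusted p = 0.156 with an estimated correlation). Of 8 photosynthesis genes 4 fell, and 5 when adjusted over the list alone (median -0.90, camera adjusted p = 0.00122, and adjusted p = 0.202 with an estimated correlation). The SPX domain list (4 of 7 rose, also when adjusted over the list alone) and the membrane lipid list (2 of 5 rose, also when adjusted over the list alone) had camera adjusted p = 0.00156 and 0.00199, and each had adjusted p = 0.148 with an estimated correlation. Of 12 heavy metal ATPase, MTP and COPT genes 2 fell, and 6 when adjusted over the list alone (camera adjusted p = 0.00777, and adjusted p = 0.156 with an estimated correlation). Histones (0 of 5 passed, 3 higher when adjusted over the list alone) had camera adjusted p = 0.0153, and adjusted p = 0.281 with an estimated correlation. Ribosomal proteins (1 of 25 fell, 2 rose and 3 fell when adjusted over the list alone) shifted upward as a list, with 20 of 25 above 0 and a median of 0.26. They had camera adjusted p = 0.0166, and adjusted p = 0.163 with an estimated correlation. Protein phosphatases 2C (1 of 55 fell, also when adjusted over the list alone) had camera adjusted p = 0.02, and adjusted p = 0.209 with an estimated correlation.

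In all, 2200 probe sets changed in the combined deficiency, 1184 upward and 1016 downward, 929 and 725 of them by at least 2-fold. The share called upward was 53.8%, against 29.7% with each array centred on its own median and 64.4% with the deposited scaling alone. The count was 5 and 6 without replicate 1 or 2 of the combined deficiency, 65 and 19 without control replicate 1 or 2, 74 without either Fe-deficiency array and 651 and 617 without P deficiency replicate 1 or 2. It was 0 in a limma fit on the 4 arrays of these groups alone, where 9526 probe sets had an unadjusted p below 0.05.

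The effect of Fe was measured again in roots without P, as the combined deficiency against P deficiency. Of the named genes LTP2-B rose from 152 ± 1.72 to 1274 ± 52.0 (log2 change 2.94, SE 0.135, limma adjusted p = 0.0134), and a probe set of OsMT-I-2c from 2493 ± 168 to 9944 ± 173 (1.99, SE 0.136, adjusted p = 0.034). The other LTP2-B probe sets stood at 76.0 in P deficiency and 383 in the combined deficiency, and at 36.2 and 14.2. Of the 10 iron acquisition genes 0 passed over all probe sets and 4 were higher when adjusted over the list alone (median 0.35, camera adjusted p = 3.05e-05, and adjusted p = 0.139 with an estimated correlation). OsNAAT1 stood at 4005 in P deficiency and 8856 in the combined deficiency (1.14, adjusted p = 0.107), OsNAS2 at 6019 and 10740 (0.84, adjusted p = 0.172) and OsYSL15 at 536 and 617 (0.20, adjusted p = 0.765).

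A further 10 lists were called in this comparison with 0 members passing over all probe sets at the 1 probe set per gene used for lists. The OsMT-I-2c probe set above is another one of its gene. Diterpenoid phytoalexin genes had 5 of 19 higher when adjusted over the list alone (camera adjusted p = 0.000333, and adjusted p = 0.139 with an estimated correlation), with CYP99A3 (LOC4335091) at 1363 and 4473. Pathogenesis-related genes had 5 of 11 higher when adjusted over the list alone (camera adjusted p = 0.00383, and adjusted p = 0.253 with an estimated correlation) and WRKY genes 3 of 6 (camera adjusted p = 0.00961, and adjusted p = 0.229 with an estimated correlation). Metallothioneins, with 1 of 7 higher when adjusted over the list alone, had camera adjusted p = 0.00961, and adjusted p = 0.229 with an estimated correlation. The YSL and Nramp list (2 of 21 when adjusted over the list alone), the ZIP list (0 of 10) and the heavy metal ATPase, MTP and COPT list (1 of 12) shifted upward, with camera adjusted p = 0.0491, 0.0491 and 0.0268, and adjusted p = 0.253, 0.253 and 0.246 with an estimated correlation. Mitotic genes (median -0.27, camera adjusted p = 3.05e-05), ribosomal proteins (-0.14, camera adjusted p = 0.0119) and cellulose synthases (-0.15, camera adjusted p = 0.0491) shifted downward with 0 members passing when adjusted over the list alone. These had adjusted p = 0.139, 0.229 and 0.246 with an estimated correlation. In all, 18 probe sets changed, 13 upward and 5 downward. The count was 8 without either control array and 0 without any one of the other 6 arrays, with 4942 to 5536 probe sets at an unadjusted p below 0.05 in limma. It was 0 in a limma fit on the 4 arrays of these groups alone, where 5217 probe sets had an unadjusted p below 0.05.

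The effect of P was measured again in roots without Fe, as the combined deficiency against Fe deficiency. Phosphate starvation genes rose in 8 of 9 cases, also when adjusted over the list alone (median 3.26, camera adjusted p = 7.41e-08, and adjusted p = 0.0684 with an estimated correlation). OsPT6 went from 32.7 ± 0.136 to 950 ± 1.85 (log2 change 4.31, SE 0.382, limma adjusted p = 0.0216) and OsMGD2 from 64.1 ± 5.91 to 1295 ± 119 (4.03, SE 0.157, adjusted p = 0.0031). OsSPX5 (3.74), OsSPX3 (3.47) and OsSPX2 (3.26) were the other largest named rises. The largest named falls were those of GLUA-3 (LOC4333164), a glutelin storage protein, from 258 ± 19.3 to 15.1 ± 16.6 (-3.25, adjusted p = 0.0298), the trehalose-phosphate phosphatase OsTPP7 (LOC4346885, -2.78), OsGLU15 (-2.66), the chitinase OsChia4a (LOC4336265, -2.53) and the KNOTTED-type homeobox gene Oskn1 (LOC4333973, -2.38).

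Of the iron acquisition genes 2 of 10 fell, and 6 fell and 1 rose when adjusted over the list alone (median -0.47, camera adjusted p = 0.0311, and adjusted p = 0.23 with an estimated correlation). They were OsYSL15, from 1862 to 617 (-1.57, adjusted p = 0.0278), and OsYSL9, from 1581 to 697 (-1.17, adjusted p = 0.0344). Mitotic genes rose in 6 of 42 cases, and 19 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.02e-07, and adjusted p = 0.0684 with an estimated correlation). Cellulose synthase and related genes rose in 7 of 29 cases, and 11 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.171 with an estimated correlation). The SPX domain list (4 of 7 rose), the membrane lipid list (2 of 5 rose) and the heavy metal ATPase, MTP and COPT list (2 of 12 fell) each had camera adjusted p = 0.00296, and adjusted p = 0.167 with an estimated correlation. Adjusted over the list alone the counts were 4, 2 and 5. Of 8 photosynthesis genes 1 fell, and 4 when adjusted over the list alone (camera adjusted p = 0.0297, and adjusted p = 0.284 with an estimated correlation). Ribosomal protein genes shifted upward as a list, with 20 of 25 above 0, while 0 passed, and 2 rose and 3 fell when adjusted over the list alone (median 0.28, camera adjusted p = 0.0196, and adjusted p = 0.191 with an estimated correlation).

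In all, 1293 probe sets changed between the combined deficiency and Fe deficiency, 776 upward and 517 downward. The share called upward was 60%, against 27.6% with each array centred on its own median. The count was 60 without either control array, 15 without either P-deficiency array and 2 without any one of the other 4 arrays. It was 0 in a limma fit on the 4 arrays of these groups alone, where 10491 probe sets had an unadjusted p below 0.05.

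The 2 by 2 design also allowed a test of whether the combined effect differed from the sum of the single effects. The interaction passed for 23 probe sets, 4 above 0 and 19 below 0, in 12 genes with a known probe set. Without probe sets marked as shared, that of LTP2-B among them, the interaction passed for 5, all below 0. With a trend in eBayes it passed for 355, 195 above 0 and 160 below 0, so the lean below 0 depends on that choice. The named ones were ACA1, at 4.84 ± 2.70 in the control, 48.5 ± 9.43 in P deficiency, 77.5 ± 7.08 in Fe deficiency and 7.02 ± 0.347 in the combined deficiency (-3.65, SE 0.251, limma adjusted p = 0.0322), and LTP2-B (-3.01, SE 0.191, adjusted p = 0.0271). This LTP2-B value is that of 1 probe set. In the same order of groups its other probe sets stood at 30.1, 76.0, 680 and 383, and at 21.2, 36.2, 59.6 and 14.2. The iron acquisition list had 0 members passing and 4 below 0 when adjusted over the list alone (median -0.85, camera adjusted p = 0.00016, and adjusted p = 0.273 with an estimated correlation). OsYSL15 gave -1.78 (SE 0.246, adjusted p = 0.167). The phosphate starvation list had 0 members passing and 3 below 0 when adjusted over the list alone (median -0.24, camera adjusted p = 0.0119, and adjusted p = 0.273 with an estimated correlation), with OsSPX3 at -2.51 (adjusted p = 0.214). The interaction count was 5 without either control array and 0 without any one of the other 6 arrays, with 4251 to 5220 probe sets at an unadjusted p below 0.05 in limma.

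Across all 57194 probe sets, the log2 effect of P with Fe correlated with the effect of P without Fe at a Pearson r of 0.385 (Spearman 0.355), and 64% had the same sign. These contrasts share no array. For the Fe effect with and without P the r was 0.0472 (Spearman 0.0359) and 51.7% had the same sign. Among the 28597 probe sets at or above the median level the r was 0.669 for P and 0.129 for Fe. Of the 4736 probe sets called for P with Fe present, 4287 had the same direction with Fe absent. Their median log2 size was 1.16 with Fe and, taken along the first direction, 0.667 without Fe (r 0.764). Of the 71 called for Fe with P present, 54 had the same direction with P absent and 67 had a smaller change there. Their median size was 2.42 with P and, taken in the same way, 0.731 without P (r 0.499). These probe sets were chosen for passing in the first contrast of each pair, so part of the smaller size comes from that choice.

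The P and Fe deficiencies shared 34 probe sets called upward, where 2.54 would be shared by independent lists, and 8 called downward, where 0.446 would be. These comparisons share the control arrays. Over probe sets at or above the median level their effects correlated at 0.325, against 0.5 in 100 simulations of unchanged groups with shared controls, and their covariance was 0.0882, against 0.0355 in the simulations. With the P effect taken against 1 control array and the Fe effect against the other, so that they share no array, the correlation was 0.116 and 0.131 for the 2 ways of doing so, the covariance 0.0379 and 0.0425, and 50.5% and 52.2% had the same sign.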

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

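The tests of grain tissue and of a single faulty probe set were written before their results were seen, and the other 5 tests below were chosen only after. The readings of those first 2 tests and of the test of dividing tissue were changed after the results were seen, from argued against to open.

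The interaction of P and Fe deficiency tests a difference between groups directly, and it picked out 10 results. It passed for 23 probe sets, 19 of them below 0, and with a trend in eBayes for 355, of which 160 were below 0. Among named genes ACA1 gave -3.65 and LTP2-B -3.01 on the log2 scale, each with both arrays of Fe deficiency above both control arrays. As list medians, iron acquisition gave -0.85, the phosphate starvation response -0.239, SPX domain proteins -0.239 (camera adjusted p = 0.0448), metallothioneins -0.301 (camera adjusted p = 0.0208) and cytosolic ribosomal proteins -0.137 (camera adjusted p = 0.0448), each with adjusted p = 0.273 with an estimated correlation. Photosynthesis genes gave 0.606 (camera adjusted p = 0.00016) and WRKY factors 0.712 (camera adjusted p = 0.0152), each also with adjusted p = 0.273 with an estimated correlation. The control enters the interaction with a plus sign, so high values in the control arrays alone raise it and low ones lower it. Medians in P, Fe and combined deficiency against the control were -1.26, -0.37 and -0.90 for photosynthesis and -0.464, -0.00662 and -0.213 for WRKY. High control arrays were not told apart from an interaction. Of these 7 lists 0 had a member passing the limma interaction test over all probe sets, where 5011 probe sets had an unadjusted p below 0.05. Adjusted over the list alone, 2 SPX and 2 metallothionein genes were below 0 and 4 photosynthesis and 3 WRKY genes above. In the WRKY list OsWRKY71 stood at 2374 in the control and 603 in P deficiency, and at 1430 in Fe deficiency and 922 in the combined deficiency.

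AMY1.1 and LTP2-B had the 2 largest named rises in Fe-deprived roots. Grain tissue left on those roots may add such transcripts, and 13 markers of grain, listed after AMY1.1, LTP2-B and GLUA-3 had been seen, had a median change of 0.144 (interquartile range 0.202) with 0 passing upward in limma, where 4767 of all probe sets had an unadjusted p below 0.05. That met the bound set in advance against this explanation, and the 4 other alpha-amylases among the 13, AMY1.2 (-0.0394), AMY1.3 (0.144), AMY1.4 (0.166) and AMY1.5 (0.249), were near 0 as well. It is left open because 8 of the 13, with AMY1.2, AMY1.3 and AMY1.4 among them, lay below the median normalized intensity of 57.7 in both groups, where a marker decides little, and because 1 of the 13, the cysteine proteinase gene OsSAG12 (LOC4324982), stood at 62.3 in the control and 926 in Fe deficiency (3.86, SE 0.577), though it did not pass (adjusted p = 0.112). One faulty probe set could not give both rises, which were read on separate probe sets. For LTP2-B alone, both other probe sets rising by more than 1 was set in advance to argue against a faulty probe set. They changed by 4.11 and 1.05, and it stays open for LTP2-B as the smaller lay within its SE of 0.286 of that bound. Binding of another changing transcript to these probe sets was not tested. A response of root cells to Fe shortage was not tested apart from these.

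The median iron acquisition response was smaller without P over 10 genes, a call lost with an estimated correlation (adjusted p = 0.273). Saturation of bright probe sets was argued against by the 7 members with group means under 5000, whose median interaction was -0.81 (interquartile range 0.44). Scaling between arrays was argued against by the median of -0.847 with the deposited scaling alone. That P deprivation eased the Fe shortage may explain it, but the interaction of OsVIT2, at -0.95 in Fe deficiency (adjusted p = 0.32), was 0.0494 (SE 0.34), too wide a spread to decide. Members differed in how the response became smaller. OsNAS1 stood at 8097 in the control, 14640 in P deficiency, 25050 in Fe deficiency and 24480 in the combined deficiency. OsYSL15 stood at 460, 536, 1862 and 617 in that order. Between the combined deficiency and Fe deficiency 2 of the 10 fell, and 6 fell and 1 rose when adjusted over the list alone.

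The mitotic and cellulose synthase lists were called upward in P-deprived roots, with 17 of 42 and 10 of 29 genes rising and 1 of each falling, and had adjusted p = 0.0928 and 0.171 with an estimated correlation. Scaling between arrays as the whole cause was argued against for the mitotic list by its median of 0.738 with the deposited scaling alone and 0.513 with each array centred on its median, while the cellulose synthase list, at 0.511 and 0.285, had no bound set and stays open. A larger share of dividing tissue at the expense of mature tissue stays open, as the 3 xylem cellulose synthases, which rose with a median of 1.41, belong to the pattern itself and were picked after their rise was seen. OsLsi1 (-0.67) and OsLsi2 (-1.31), markers of exodermis and endodermis, fell, and OsCASP1 (1.77), a marker of endodermis, rose. A change in the make-up of the root, with more of both dividing tips and xylem, may underlie it and was not tested, nor was a change within cells.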

How the results depend on the processing

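The deposited scaling alone was chosen only after the values were seen, as was the choice of which list results to follow singly. The counts of changed probe sets depend strongly on how the spread is estimated. Of the named genes and list calls followed, 0 changed sign in an alternative. The direction with the larger share of called probe sets turned in several, while sign changes of single probe sets were not counted. Centring each array on its median gave 32.8% upward for P deficiency against 51%, 29.7% for both against the control against 53.8%, and 27.6% for both against Fe deficiency against 60%. A trend in eBayes gave 54.9% above 0 for the interaction against 17.4%. Shares of 48.3% to 49.7% for P deficiency and 48.9% to 49.3% for both against the control came from the trend, 1 probe set per gene and the median filter, and for P deficiency also from the 25th percentile filter and a pseudocount of 64. Of 870 repeats of list calls 700 still passed, and of 715 repeats of named genes 364 still passed. Counts below are in the order P deficiency, Fe deficiency and both against the control, both against P deficiency, both against Fe deficiency, and interaction.

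With only the arrays of the contrast each of the first 5 counts was 0 in limma (11222, 5009, 9526, 5217 and 10491 at an unadjusted p below 0.05), as fewer arrays left fewer degrees of freedom. Leaving out each array in turn gave 3 to 2990, 0 to 10, 5 to 651, 0 to 8, 2 to 60 and 0 to 5. The report names the arrays. A replicate block gave 2385, 14, 107, 0, 19 and 0 (5399 and 4815 at an unadjusted p below 0.05 for the limma counts of 0). With that block 18 of 20 named genes of P deficiency, 2 of 11 of Fe deficiency and 0 of 2 of the interaction still passed. The deviations of equal replicate numbers correlated at -0.0538 to 0.054, so no shared shift was seen. Whether equal numbers were grown or handled together cannot be told from this. An adjusted p under 0.01 gave 615, 10, 76, 0, 23 and 0 by its stricter threshold (5806 and 5011 at an unadjusted p below 0.05 in limma for the 0s), and a minimum log2 change of 1 gave 3097 for P deficiency.

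Probe sets at or above the median level gave 8834, 264, 6071, 241, 5159 and 58, and those at or above the 25th percentile 135, 3348, 46, 2389 and 39 from Fe deficiency on. A trend in eBayes gave 9121, 417, 6642, 707, 5741 and 355. With 1 probe set per gene the counts from Fe deficiency on were 177, 4376, 188, 3898 and 70. Without probe sets marked as shared, Fe deficiency had 43 and the interaction 5. A pseudocount of 1 gave 3082, 32, 843, 10, 205 and 6, and 64 gave 7473, 213, 4506, 118, 3614 and 63. Signal over background was not measured. Centring each array on its median gave 46 for Fe deficiency, 45 of them shared with the 71, and 783 for both against Fe deficiency. It moved the median of all probe sets in P deficiency from -0.0175 to -0.147. Array weights gave 2312 for both against Fe deficiency. For pseudocounts, centring, weights and the trend the cause was not tested.

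The r for the agreement of the P effect with and without Fe was 0.669 at or above the median level, 0.403 with the deposited scaling alone and 0.324 to 0.361 with an array left out. The r for the agreement of the Fe effect with and without P was 0.129 at or above the median level and 0.0207 to 0.0564 with an array left out.

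Camera with an estimated correlation left 0, 1, 0, 0, 0 and 0 lists called. It gave adjusted p = 0.0986 for phosphate starvation in P deficiency and 0.273 for the iron acquisition interaction. Both lists had an estimated correlation below the preset one, so a stronger correlation between genes does not account for these larger values. Fry called 32, 12, 35, 19, 32 and 13. With an array left out the lists called numbered 9 to 12, 6 to 8, 11 to 12, 6 to 11, 6 to 10 and 3 to 7. Of 61 list calls, 53 were called with the deposited scaling alone and 47 to 55 with an array left out.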

Other observations

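The values here were chosen after they were seen, and no test was added for them. Single genes outside the called lists also changed in P deficiency, and none of the tested lists they came from was called. The laccases LAC10 (LOC4332400) and LAC4 (LOC4327500) rose from 1323 to 5523 (2.05, limma adjusted p = 0.00682) and from 219 to 922, where the phenylpropanoid list had camera adjusted p = 0.757. The peroxidase PRX74 (LOC4339222) rose from 2515 to 11940 (2.24, adjusted p = 0.00432) and the auxin efflux carrier gene OsPIN2 (LOC4341736) from 425 to 1723 (1.98, adjusted p = 0.0111). The peroxidase list was too small to test and the auxin list had camera adjusted p = 0.249. OsSWEET11 (LOC4346153), a sugar transporter, rose from 41.6 to 198 (1.89, adjusted p = 0.0103), and the aquaporin gene OsTIP2;1 (LOC4330207) from 8744 to 20710 (1.24, adjusted p = 0.00941), where the sugar and starch list had camera adjusted p = 0.968 and the aquaporin list 0.702. The cation transporter genes OsHKT1;5 (LOC4327757, -1.33) and OsHAK16 (LOC4333298, -1.75) and the ammonium transporter gene OsAMT1;2 (LOC4330008, -1.40) fell, where the nitrate and ammonium list had camera adjusted p = 0.757. Of 28 potassium transport genes 5 fell and 0 rose, and 5 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.283).

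Of the 12 genes with an interaction, 11 were below 0. Of these, 6 passed upward against the control in both single deficiencies, 2 of which did not pass upward in the combined deficiency. The control enters the interaction and the single effects with opposite signs, so a low control value favours this pattern. Without probe sets marked as shared, such as those of LOC4327106 and LOC4352472, the interaction passed for 5 probe sets. LOC4327106 stood at 98.3 in the control, 4501 in P deficiency, 80.6 in Fe deficiency and 83.5 in the combined deficiency (interaction -5.27, SE 0.339, adjusted p = 0.0271). LOC4341223 had 348 and 116 in the single deficiencies against 7.65 in the combined one (-6.75, adjusted p = 0.0167), and LOC4352472 had 1145, 3096 and 493 (-6.61, adjusted p = 0.0271). LOC4349197 was the only one of the 12 above 0, at 137 in the combined deficiency and 8.07 or less in each other group (2.72, adjusted p = 0.0463).

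Array quality measures differed within and between groups, and their differences were not separated from those of the treatments. The 3' to 5' difference of the gapdh control transcript was 4.23 and 0.187 on the log2 scale in the 2 control arrays and 5.07 and 2.44 in Fe deficiency, with group means of 2.21 in the control, 0.40 in P deficiency, 3.76 in Fe deficiency and 1.63 in the combined deficiency. The BioB spike had a mean of 963 in the control, 915 in P deficiency, 554 in Fe deficiency and 788 in the combined deficiency, and the cre spike 29445, 29850, 18664 and 25758.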
